A study of Danio rerio with 6 samples.

How the data were processed

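RNA was measured on 6 single-colour oligonucleotide arrays of the zebrafish, 1 array per condition. Per the labels' protocols, GFP-positive cells were sorted by flow cytometry after embryos had been dissociated, RNA was amplified in 2 rounds with the AmpTec ExpressArt Nano kit, and the copies were labelled with Cy3. The arrays held whole embryos at 18 and 24 hours post fertilisation (hpf), Fli1 reporter cells at 18, 24 and 28 hpf, and Flk reporter cells. Groups were taken from the sample titles. For the Flk cells the title and the series design give 18 hpf and the sample description gives 24 hpf, so 18 hpf was used and comparisons with the 24 hpf arrays were kept as an alternative. The label for the source of the RNA reads whole larvae on all 6 arrays, the sorted cells included, and the title decided. The extraction protocol names the Tg(Fli1:EGFP) line alone, so that the Flk line rests on the title and description of its sample and on the series design.

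Each scanner file gives the intensity of a spot and of its local background at scan settings named 45, 55 and 65, per the file headers. The authors also deposited a background-subtracted intensity joined over the scan settings, and the same intensity divided by 1 number per array, which equals the geometric mean of the detected spots. The deposited value table holds this scaled intensity on a linear scale, with column medians of 0.801 and 0.816 for whole embryos at 18 and 24 hpf, 0.922, 0.856 and 0.922 for Fli1 cells at 18, 24 and 28 hpf, and 0.869 for Flk cells. It differed from the scaled scanner column by at most 4.3e-07, so its scale and direction are known, and its genes were not centred. The files also give the ratio of spot to background at each scan setting and a flag score per spot, per the file headers, and the meaning of the flag codes is not given in the sources used here. Nor are the scanner and the image software.

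The array had 14784 spots, of which 14067 were zebrafish probes, 544 were empty and 173 were Arabidopsis control spots. Names came from the RefSeq gene table (assembly GRCz12tu), used for names only. Of the zebrafish probes, 7702 were named by accession, 24 by an older accession, 416 by clone name, 49 by the gene name in their description and 220 by a description shared with a named probe, which left 5656 unnamed. The 8411 named probes covered 5036 symbols, 1850 of them with more than 1 probe. Probes with a flag on any array (68) were left out, and saturated spots were kept.

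Spot and background intensity at scan setting 55 were corrected with normexp (offset 50) and quantile normalized between arrays in limma 3.58.1 under R 4.3.3. A probe was above background where its spot exceeded the 95th percentile of the Arabidopsis spots of that array, a limit chosen after the control spots were seen and before any result. A gene was represented by its probe with the highest mean signal, and unnamed probes were kept singly. Genes and unnamed probes above background on at least 1 array were analysed, 6006 in all and 3233 of them named. The fli1a gene stands under the symbol fli1. The list symbol dld was left out, because on this array it names dihydrolipoamide dehydrogenase.

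Pairs of arrays were compared by the log2 difference. A gene counted as different at 2-fold or more with the brighter array above background. Where the dimmer side was below background, or the brighter side saturated, the fold is given as at least N-fold, against the lowest signal above background on the dim array where that is the higher value, and no fold is given where both sides were below background or both saturated. Fixed lists of marker genes and pathways (21 lists) were described by the median log2 difference of their measured members and its percentile among 10000 random lists of the same size, matched on mean signal in 20 bins. A list was said to stand apart where its median lay in the outer 2.5% at either end. The percentiles were not adjusted for the number of lists and comparisons, so some lists would stand apart by chance. Lists with fewer than 5 measured members have counts only. The random lists come from the same arrays, so the percentile is relative to any shift of all genes.

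The 4 sorted arrays were compared with the 2 whole-embryo arrays by limma (lmFit and eBayes, 4 residual degrees of freedom) with Benjamini-Hochberg adjustment at 0.05. Lists were tested with camera at the preset correlation of 0.01 and with an estimated one, and with fry, which asks whether the members of a list move one way on balance. On simulated data for this comparison, with 200 of 6006 genes changed, limma found 8.1% of genes changed 2-fold, 91.4% of those changed 4-fold and 98.5% of those changed 8-fold, and it called 7 of 5806 unchanged genes. The noise there was normal, independent and equal on all arrays, at the variance limma had estimated per gene. Effects of stage, line or array shared between genes were not simulated, so the real arrays can give lower rates of finding. The list percentiles were tried on simulated differences, drawn independently per gene with an SD of 1, and only the signal levels used for matching came from the arrays. There 7 of 100 random lists of 16 genes stood apart with no shift added, and 90 of 100 did with a shift of 1 added. Members of a real list can move together, which was not simulated, so these rates need not hold for the array comparisons.

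Genes named in the text follow a rule fixed before the data were examined. It takes the reporter genes, up to 5 members of each list by the mean of the stage-matched Fli1 differences, the 10 highest and 10 lowest genes of that mean that passed limma in all 4 sorted arrays (filled from genes 2-fold different at both stages), the 10 at each end of the change from 18 to 28 hpf in Fli1 cells and from 18 to 24 hpf in whole embryos, and the 10 at each end of Flk against Fli1 cells. Other list members given as examples were chosen after their values were seen. Alternatives were no background correction, scaling to the 75th percentile, the authors' scaled intensity, other filters on dim probes, the mean over the probes of a gene, leaving out each array, a stage term and a second p threshold of 0.1. Added after the data were seen were the empty spots as background, the joined scan settings, counts over both stages and a fit without the 2 sorted arrays of weakest signal. Figures were drawn with matplotlib 3.10.9, and lists were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.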

Results

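The study measured gene expression during vascular development of the zebrafish embryo. RNA of whole embryos at 18 and 24 hpf was set beside RNA of cells that a flow sorter had collected for their GFP signal from Tg(Fli1:EGFP) embryos of 18, 24 and 28 hpf, in which regulatory sequence of the transcription factor gene fli1 drives EGFP in endothelial and blood cells and in part of the neural crest. A 6th array held GFP-positive cells of a Flk reporter line, named for the vascular endothelial growth factor (VEGF) receptor gene now called kdrl. No condition had a replicate, so a difference between 2 arrays has no replicate check. The p-values from limma ask whether the difference between fractions exceeds the spread between the arrays inside each fraction. That spread mixes stage, reporter line (in the sorted fraction) and the error of single arrays.

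Signals differed in strength between arrays. Probes above background made up 37.5% and 39.4% of 13999 on the whole-embryo arrays at 18 and 24 hpf, 24.7%, 32.5% and 32.9% on the Fli1 arrays at 18, 24 and 28 hpf, and 42.6% on the Flk array. The 99th percentile of background-subtracted intensity was 26776 and 20456 for whole embryos, 3059, 10108 and 3281 for Fli1 cells in order of stage, and 9241 for Flk cells. Between 2 arrays, the log2 difference over the 173 Arabidopsis control spots had an SD of 0.35 to 0.45. Across 6006 genes and unnamed probes, which are not independent replicates, the Spearman correlation was 0.764 between the 2 whole-embryo arrays, 0.79 between Fli1 cells at 24 hpf and Flk cells, and 0.404 between whole embryos at 24 hpf and Fli1 cells at 28 hpf. Under 75th percentile scaling the median log2 signal of all probes ran from 7.63 on the whole-embryo array at 18 hpf to 7.95 on the Fli1 array at 18 hpf, while the 99th percentile on these arrays was 14.02 and 12.26.

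Several embryonic globin and heme synthesis genes were higher in Fli1 sorted cells than in whole embryos of the same stage, and fbp1b, bhmt and the keratin krt92 were among the lower genes. The alpha globin hbae1.1 was 19.5-fold higher at 18 hpf and 4.53-fold higher at 24 hpf, and hbae3 was 14.5-fold and 6.1-fold higher. The heme synthesis enzyme urod was 7.5-fold and 5.02-fold higher, alas2, the first enzyme of that pathway in red cells, at least 5.52-fold and 4.08-fold, and drl, a zinc finger gene of the lateral plate mesoderm, at least 12.9-fold and 5.46-fold. The immediate early gene fosab was at least 20.5-fold higher at 18 hpf and at least 5.39-fold higher at 24 hpf. In the other direction, fbp1b, an enzyme of gluconeogenesis, was at least 18.7-fold lower at both stages, bhmt, which methylates homocysteine, was 7.87-fold and 32-fold lower, and krt92 was 16.4-fold and 7.15-fold lower. Also higher at both stages were phlda2 (5.86-fold and 6.18-fold), the ribosome assembly factor rpf2 (14.8-fold and 2.25-fold) and the Golgi regulator arfgap1 (6.72-fold and 4.49-fold).

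The reporter genes gave little signal. Both fli1 probes were below background on 5 arrays and above it on the Flk array alone, so no fold is given for sorted Fli1 cells. One kdrl probe was above background on all 6 arrays, and on it kdrl was 1.88-fold higher in Fli1 cells than in whole embryos at 18 hpf, 1.6-fold higher at 24 hpf, and 2.03-fold higher in Flk cells. The other 3 kdrl probes were below background on all 6 arrays.

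Among the lists fixed beforehand, the 16 erythroid genes stood apart upward at both stages, with a median log2 difference of 0.60 at 18 hpf (percentile 98.4 of random lists) and 0.97 at 24 hpf (percentile 100). At 18 hpf 5 members were at least 2-fold higher and 1 lower, and at 24 hpf 8 were higher and 1 lower. The beta globin hbbe1 was 22.8-fold higher at 18 hpf and saturated on both arrays at 24 hpf, and the lower member was the actin-capping gene tmod4, below background in Fli1 cells at 18 hpf and 2.01-fold lower at 24 hpf. The 15 endothelial and angioblast genes had medians of 0.53 (percentile 96.8, inside the random lists) and 0.47 (percentile 98.4), and at 18 hpf the percentile was 99.4 under 75th percentile scaling and 98.6 with the authors' scaled values. In this list lmo2, a transcriptional partner needed for blood and endothelium, was 2.79-fold and 1.94-fold higher, the receptor gene tek at least 1.42-fold and 2.7-fold higher, the haematopoietic regulator tal1 1.87-fold and 1.72-fold higher, and the kinase gene yes1 3.42-fold and at least 1.15-fold higher, while the arterial ligand efnb2a was 2.56-fold and 1.19-fold lower. The median of the 10 myeloid and haematopoietic progenitor genes was 0.64 (percentile 97.2) and 0.37 (percentile 85.8), with lysozyme (lyz) at least 4.52-fold and 3.77-fold higher and the leukocyte plastin lcp1 2.53-fold and 1.26-fold higher. Of 4 measured arterial genes 1 was 2-fold lower at each stage, efnb2a at 18 hpf and tbx20 at 24 hpf (3.08-fold), and none of the 4 venous and lymphatic genes differed 2-fold. The endothelial percentile at 24 hpf was 96.8 under 75th percentile scaling and 97.49 with the authors' scaled values, both inside the random lists. It was 96.99 with no background correction, 94.56 with the joined scan settings and 79.1 with the mean over the probes of each gene.

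Genes of surface epithelium were lower in Fli1 cells at both stages, and those of yolk, liver and gut stood apart at 24 hpf only. The 16 epidermis and periderm genes had a median of -0.71 at 18 hpf (percentile 0.51) and -1.54 at 24 hpf (percentile 0), with 7 members 2-fold lower and 1 higher at 18 hpf and 11 lower and 1 higher at 24 hpf. Examples were krt5 (at least 5.34-fold and 10.8-fold lower), the calcium-binding ictacalcin icn (6.31-fold and at least 16.1-fold lower) and the desmosomal protein periplakin, ppl (at least 3.16-fold and 6.25-fold lower). The 20 yolk, liver and gut genes had medians of -0.10 (percentile 30.3) and -0.34 (percentile 0.38), with 5 lower and 3 higher at 18 hpf and 8 lower and 1 higher at 24 hpf. The apolipoprotein apoa1a was 5.59-fold and 16.8-fold lower, and the fatty acid carriers fabp1b.1 (at least 12.1-fold and 17.3-fold) and fabp2 (at least 6.82-fold and 3.4-fold) were lower too. With only genes above background on all 6 arrays, the epidermis percentile at 18 hpf was 9.57 and the yolk, liver and gut percentile at 24 hpf was 3.06. Under 75th percentile scaling the epidermis medians were -1.8 at 18 hpf, with 10 members lower, and -2.18 at 24 hpf, with 12 lower. With the authors' scaled values they were -2.09 and -2.28, with the same numbers lower. Random lists matched on signal had medians of -0.62 and 0.04 under 75th percentile scaling, and of -0.89 and -0.06 with the authors' scaled values. Part of the fall at 18 hpf under these scalings was thus shared by genes of like signal.

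The 23 skeletal muscle genes stood apart at 24 hpf only. Their median was -1.01 (percentile 0), and 12 members were 2-fold lower and none higher, among them the fast troponin tnnc2.2 (9.11-fold), the parvalbumin pvalb2 (at least 6.96-fold) and the creatine kinase ckma (at least 5.14-fold). At 18 hpf the median was 0.15 (percentile 63.5). It turned to -0.13 (percentile 51.05) under 75th percentile scaling and -0.42 (percentile 45.78) with the authors' scaled values, all inside the random lists. The 6 cardiac muscle genes had medians of 0.47 and -0.24, inside the random lists, with tnnc1a 2.11-fold higher at 18 hpf (a log2 difference of -0.07 with the mean over its probes).

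The 24 dissociation and stress response genes stood apart at 24 hpf, with a median of 0.40 (percentile 98.4) and 5 members 2-fold higher and none lower. At 18 hpf their median was 0.42 (percentile 97.3, inside the random lists), with 7 higher and 2 lower. Under 75th percentile scaling the value at 18 hpf was 0.40 (percentile 98.3), with 4 higher and 4 lower. With only genes above background on all 6 arrays the percentile at 24 hpf was 76.2. The endoplasmic reticulum chaperone hspa5 was 5.11-fold and 1.78-fold higher and the stress factor atf3 at least 3.78-fold and 2.46-fold higher, whereas the small heat shock protein hspb1 was 10.3-fold and 1.58-fold lower. The 72 ribosomal protein genes had a median of -0.53 at 18 hpf (percentile 0.01), with 20 members lower and 3 higher, and 0.11 at 24 hpf (percentile 9.57). Under 75th percentile scaling these medians were -2.05, with 56 members lower, and -0.02, and with the authors' scaled values -2.48, with 66 lower, and -0.13. Random lists matched on signal had medians of -1.33 and 0.01 under 75th percentile scaling, and of -1.66 and -0.07 with the authors' scaled values. Much of the fall at 18 hpf under these scalings was thus shared by genes of like signal. Examples were rpl19 (5.67-fold and 1.23-fold lower) and rps6 (at least 4.59-fold and 2.37-fold lower).

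The other lists did not stand apart at 18 hpf, and of those only cell cycle did at 24 hpf. The 34 cell cycle genes had medians of 0.14 and -0.16 (percentile 0.79 at 24 hpf), and the value at 18 hpf was -0.29 under 75th percentile scaling and -0.40 with the authors' scaled values. Medians at 18 and 24 hpf were 0.22 and 0.23 for 15 neural crest and pharyngeal arch genes, -0.11 and -0.09 for 30 neural genes, 0.02 and 0.12 for 26 hox genes, 0.14 and 0.16 for 6 pronephros genes (-0.06 at 18 hpf with the authors' scaled values), and 0.41 and 0.05 for 12 extracellular matrix and basement membrane genes (-0.21 at 24 hpf with the authors' scaled values). The 15 genes of the VEGF and Notch pathway had medians of 0.19 and 0.33, with -0.09 and -0.24 at 18 hpf under the 2 other scalings, and in this list the Notch target her2 was at least 2.43-fold and 4.21-fold lower and the VEGF co-receptor nrp2b 2.84-fold and 1.68-fold higher. In the matrix list lamb1a, a laminin chain, was at least 2.17-fold higher at 18 hpf, with a log2 difference of -1.36 under 75th percentile scaling. The lens crystallin cryba1b was at least 8.19-fold lower at 24 hpf, 1 of 2 measured lens genes. Of the 3 hatching gland genes xbp1 was 2-fold lower at 24 hpf (2.18-fold), and neither notochord gene differed 2-fold.

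In counts, 596 genes and unnamed probes were at least 2-fold higher in Fli1 cells than in whole embryos at 18 hpf and 785 lower, and 259 were higher and 467 lower at 24 hpf. Higher ones made up 43.2% at 18 hpf and 35.7% at 24 hpf, against 24.1% and 29.0% under 75th percentile scaling and 13.8% and 23.2% with the authors' scaled values. At both stages 90 were higher and 176 lower, where independent lists of these sizes would share 25.7 and 61, and 50 and 283 were under 75th percentile scaling. Where a gene that differed 2-fold had another probe above background, that probe had the same sign for 68.0% of 178 genes at 18 hpf and 86.3% of 95 genes at 24 hpf. It was itself 2-fold different in that direction for only 25.3% and 40% of these genes.

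**Figure D1:**
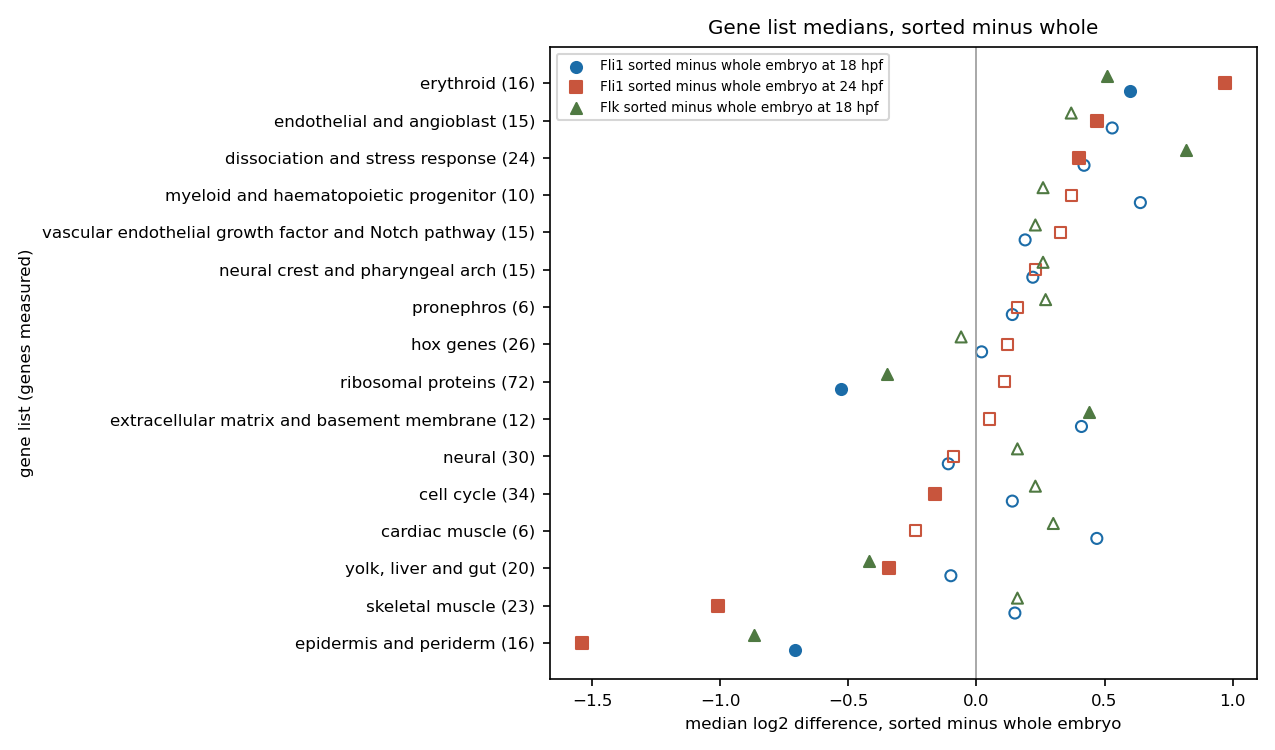
Median log2 difference, sorted minus whole embryo, of each gene list with at least 5 measured members (number in brackets), for Fli1 cells at 18 hpf (circles) and 24 hpf (squares) and Flk cells at 18 hpf (triangles). Filled symbols lie in the outer 2.5% of random lists at either end. Erythroid genes lay to the right in all 3 comparisons (0.60, 0.97 and 0.51) and epidermis and periderm genes to the left (-0.71, -1.54 and -0.87), and the positive skeletal muscle and cell cycle medians at 18 hpf in Fli1 cells turn negative under both other scalings, as do the VEGF and Notch one at 18 hpf and the ribosomal one at 24 hpf, while the pronephros median at 18 hpf and the matrix median at 24 hpf turn negative with the authors' scaled values alone.

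Over all 6 arrays, the genes that fell in the sorted fraction by limma included fatty acid carriers, metabolic enzymes and keratins. Among them, fabp1b.1 (adjusted p = 0.000166), fbp1b (0.000114), fabp2 (0.0109) and ppl (0.00563) were above background in both whole-embryo arrays and in none of the 4 sorted arrays. Where the gene was measured in the sorted cells, bhmt fell by 4.04 on the log2 scale (SE 0.45, adjusted p = 0.0109), apoa1a fell by 3.31 (SE 0.36, adjusted p = 0.00973) and krt92 fell by 3.68 (SE 0.44, adjusted p = 0.0109). The cholesterol-binding lysosomal protein gene npc2.1 (-2.70) and the sialic acid synthase nansa (-2.71) fell as well, as did krt5, saturated on both whole-embryo arrays (adjusted p = 0.0357). The transcriptional repressor tgif1 rose, by 1.70 on the log2 scale (SE 0.25, adjusted p = 0.0244). Among 6006 genes and unnamed probes, 3 rose and 44 fell at an adjusted p under 0.05. The rising ones were tgif1 and 2 probes without a symbol, 1 of them described as cytochrome c oxidase subunit I, and 24 of the falling ones were named genes, each lower on all 4 sorted arrays than on both whole-embryo arrays. Without the Fli1 array at 18 hpf none rose and 8 fell, and 75th percentile scaling gave 6 and 89. The 4 stage-matched arrays with stage as a block, on 1 residual degree of freedom, gave 112 rising and 200 falling. That fit took its variance mostly from all genes together (37.5 prior degrees of freedom, against 4.15 over all 6 arrays). Its larger counts thus rest little on the spread of each gene.

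Per list, 5 of 16 epidermis and periderm genes fell over all genes tested (ppl, krt92, krt5, krt15 and the annexin anxa1a), and adjusted over the list alone 9 fell and 2 rose, krt91 and the cadherin cdh1, which was above background on the Fli1 array at 28 hpf alone. Of 20 yolk, liver and gut genes 3 fell over all genes (fabp1b.1, apoa1a and fabp2), and adjusted over the list alone 8 fell, the fibrinogen chains fgg and fgb among them, and 2 rose, the transferrin gene tfa (1.03) and the pancreatic factor pdx1, which was below background on both whole-embryo arrays and on the Fli1 arrays at 18 and 24 hpf. No dissociation and stress response gene passed over all genes, and adjusted over the list alone 5 of 24 rose, namely fosab (below background on both whole-embryo arrays), hspa5 (1.58), atf3 (1.53), klf6a (1.39) and junba (1.03). In the VEGF and Notch list, adjusted over the list alone, kdrl rose (0.95, SE 0.26) and her2, below background on all 3 Fli1 arrays, fell, and over all genes neither passed (adjusted p = 0.15 for kdrl and 0.132 for her2). The retinoic acid binding gene crabp1a of the neural list and hoxc11a of the hox list (adjusted p = 0.0141) fell over all genes. In the endothelial, erythroid, myeloid, ribosomal, muscle, neural crest, pronephros, cell cycle and matrix lists no gene passed over all genes or within that list alone. The endothelial list also holds kdrl, so the call of kdrl depends on the list it was adjusted in.

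Of the list tests, camera gave adjusted p = 0.000279 for epidermis and periderm (downward), 0.00796 for ribosomal proteins (downward) and 0.0279 for erythroid genes (upward) at the preset correlation. With an estimated correlation these were adjusted p = 0.164, 0.593 and 0.593, and no list passed. Without the whole-embryo array at 18 hpf the preset correlation gave adjusted p = 0.13 for ribosomal proteins and 0.251 for erythroid genes. By fry, epidermis and periderm genes moved down (adjusted p = 0.00674) and endothelial and angioblast genes moved up (adjusted p = 0.0193, median 0.57). With stage as a block on the 4 stage-matched arrays these were adjusted p = 0.401 and 0.381, and with a stage term and the Flk array at 24 hpf 0.0775 for both. The endothelial value lay above 0.05 without any 1 of 4 arrays, the highest being 0.104 without the whole-embryo array at 24 hpf. Yolk, liver and gut genes (0.0537) did not pass. For hox genes the median was 0.16 while camera and fry, which did not pass, pointed down.

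**Figure D2:**
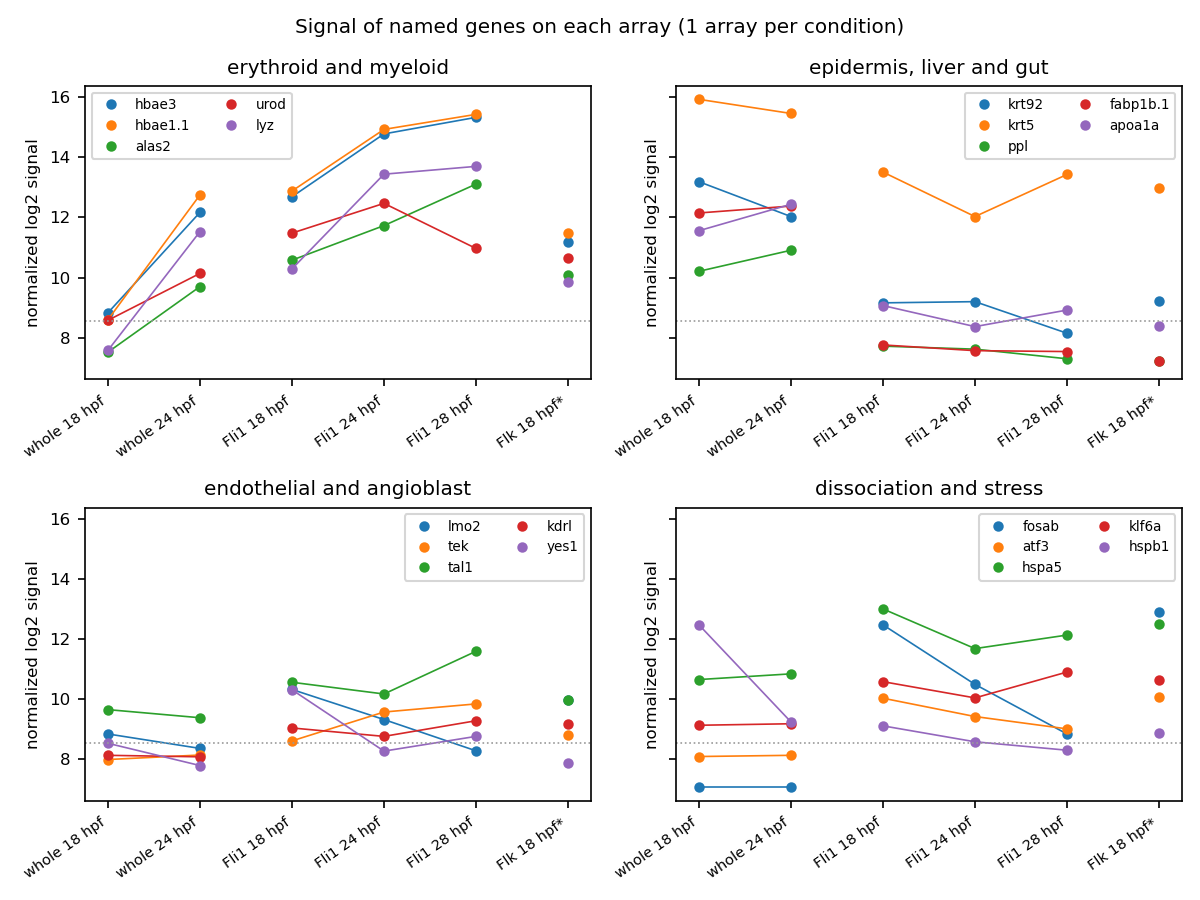
Normalized log2 signal of 20 named genes on each of the 6 arrays, 1 array per condition, in panels for erythroid and myeloid, epidermis with liver and gut, endothelial, and stress genes. Lines join stages of one fraction, the dotted line at 8.55 is the highest of the 6 lowest signals above background, and the asterisk marks the Flk array, whose stage is given as 18 hpf by the title and 24 hpf by the description. The globins hbae3 and hbae1.1 lie higher in Fli1 cells than in whole embryos at both 18 and 24 hpf, and fabp1b.1 and ppl lie below the dotted line in all sorted arrays.

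Flk sorted cells were set against whole embryos at 18 hpf, the stage their title gives. Among stress genes, fosab was at least 27.9-fold higher, hspa5 3.61-fold, the chaperone gene hsp90ab1 3.98-fold and atf3 at least 3.9-fold, and the 24 members had a median of 0.82 (percentile 100), with 9 members 2-fold higher and 3 lower. The 16 erythroid genes had a median of 0.51 (percentile 99.7), with hbbe1 8.51-fold, hbae1.1 7.5-fold and hbae3 5.16-fold higher. Epidermis and periderm genes had a median of -0.87 (percentile 0; -1.49 under 75th percentile scaling and -1.52 with the authors' scaled values), with krt92 15.6-fold and krt5 at least 7.76-fold lower. Yolk, liver and gut genes had a median of -0.42 (percentile 0.32), with apoa1a 8.99-fold and fabp1b.1 at least 18.1-fold lower. The median of the 12 extracellular matrix genes was 0.44 (percentile 98.9), of the 72 ribosomal protein genes -0.35 (percentile 0.04) and of the 15 endothelial and angioblast genes 0.37 (percentile 96.2). With the mean over the probes of a gene the matrix percentile was 97.0 (median 0.29) and the ribosomal one 2.97 (median -0.09), both inside the random lists. Under 75th percentile scaling the ribosomal median was -1.01, with 36 members 2-fold lower, and with the authors' scaled values -1.2, with 48 lower, against 15 lower after quantile normalization. Random lists matched on signal to the ribosomal genes had medians of -0.57 and -0.76 under these other scalings, in that order. The yolk, liver and gut percentile was 3.12 with the authors' scaled values and 9.33 with only genes above background on all 6 arrays, and the erythroid one was 96.96 with no filter on dim probes. In all, 412 genes and unnamed probes were 2-fold higher and 404 lower, with 50.5% higher, 37.4% under 75th percentile scaling and 34.2% with the authors' scaled values. Against whole embryos at 24 hpf, the stage the description gives, 377 were higher and 380 lower, the erythroid median was -0.09 the yolk, liver and gut percentile 2.7 and the matrix percentile 32.3, while stress (0.64) and epidermis (-1.49) kept their sign. In that comparison endothelial and angioblast genes (0.47, percentile 98.9) and VEGF and Notch genes (0.44, percentile 99.2) stood apart upward, and skeletal muscle (-0.93, percentile 0), cell cycle (-0.14, percentile 0.73) and ribosomal protein genes (-0.02, percentile 1.86, and 9.43 under 75th percentile scaling) downward.

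Between the reporter lines, erythroid genes were lower in Flk cells than in Fli1 cells of both 18 and 24 hpf. Of the genes 2-fold different from both the 18 and the 24 hpf Fli1 arrays, 76 named ones were higher in Flk cells and 16 lower. At 18 hpf the retinol dehydrogenase rdh8b was at least 22.9-fold higher and zgc:63470 at least 99.7-fold, the forkhead factor foxb1b at least 6.98-fold, the crest and cartilage regulator sox9b at least 4.55-fold, the small GTPase rnd3a 9.77-fold, eif2b1 of translation initiation at least 7.28-fold, and the lysophosphatidic acid receptor lpar1 at least 2.44-fold. The signals of rdh8b and zgc:63470 stood out on the Flk array alone, and neither gene had another probe to check them against. The lower genes included the globins hbae3 (2.81-fold), hbbe1 (2.68-fold) and hbae1.1 (2.6-fold), drl (2.78-fold), nrp2b (3.11-fold) and the tubulin tubb5 (3.37-fold). Under 75th percentile scaling the log2 differences of hbae3, hbbe1 and hbae1.1 were -0.66, -0.71 and -0.57, short of 2-fold, and no erythroid gene was 2-fold lower at 18 hpf under either other scaling. The erythroid median was -0.41 (percentile 0.56; -0.29 under 75th percentile scaling and -0.21 with the authors' scaled values), and against Fli1 cells at 24 hpf it was -1.44 (percentile 0). The ribosomal protein median was 0.12 (percentile 99.1), with 5 members 2-fold higher, and turned to -0.13 (percentile 0.39) against Fli1 cells at 24 hpf. Under 75th percentile scaling these medians were 0.91, with 29 members higher, and -0.54. With the authors' scaled values they were 1.05, with 44 higher, and -0.55. Random lists matched on signal had medians of 0.68 and -0.28 under 75th percentile scaling, and of 0.87 and -0.27 with the authors' scaled values. Much of the ribosomal rise at 18 hpf under these scalings was thus shared by genes of like signal. At 18 hpf 323 genes and unnamed probes were 2-fold higher and 220 lower, with 59.5% higher, 80.5% under 75th percentile scaling and 88.0% with the authors' scaled values. The other probe of a 2-fold gene had the same sign for 62.9% of 62 genes, the lowest share of the 8 comparisons, and was itself 2-fold different in that direction for 11.3%.

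Within Fli1 sorted cells, globin and lysozyme signals were higher at 28 than at 18 hpf, and the immediate early gene fosab was lower. From 18 to 28 hpf lyz was 10.7-fold higher, hbae3 6.23-fold, hbae1.1 5.86-fold and alas2 5.79-fold, and the heme breakdown enzyme blvrb at least 3.75-fold. The muscle calcium pump atp2a1 was 8.34-fold higher, foxb1b at least 9.62-fold, the cytotoxic cell receptor gene nccrp1 8.51-fold, the splicing protein snrnp25 8.11-fold and the BMP mediator smad9 at least 1.95-fold. Lower at 28 hpf were fosab (12.3-fold), the nuclear transport GTPase ran (7.39-fold), rps25 (17.5-fold), rpl5a (6.57-fold), the proteasome subunit psmc1a (at least 5.71-fold) and the cyclophilin ppib (6.92-fold). The chromatin binding gene cxxc1a was at least 27.8-fold lower, and its signal stood out on the 18 hpf array alone. Among the endothelial genes lmo2 was 4.1-fold and yes1 2.92-fold lower at 28 than at 18 hpf, while tek was 2.34-fold and tal1 2.05-fold higher. The median of this list was 0.03 (percentile 51.2, and -0.04 under 75th percentile scaling), with 3 members 2-fold higher and 3 lower. In all, 172 named genes were 2-fold higher and 160 lower at 28 hpf with the 24 hpf value between.

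By list, the erythroid median was 0.94 from 18 to 24 hpf (percentile 100) and 0.65 from 18 to 28 hpf (percentile 99.9), and from 24 to 28 hpf it was 0.08 (-0.10 under 75th percentile scaling and -0.18 with the authors' scaled values). Stress genes had a median of -0.40 from 18 to 28 hpf (percentile 0.24), with 5 members lower and none higher, and with no filter on dim probes the median was -0.10 (percentile 16.2). The ribosomal protein median was 0.28 from 18 to 24 hpf (percentile 100) and -0.83 from 24 to 28 hpf (percentile 0.03), where 30 of 72 members were 2-fold lower and 1 higher. Under 75th percentile scaling these medians were 1.51, with 61 members higher, and -2.21, with 60 lower, and with the authors' scaled values 1.67 and -2.30. Random lists matched on signal had medians of 1.03 and -1.44 under 75th percentile scaling, and of 1.2 and -1.46 with the authors' scaled values. Much of these ribosomal changes was thus shared by genes of like signal. From 18 to 28 hpf the ribosomal median was -0.49 (percentile 3.48, inside the random lists), with 22 lower and 2 higher. The Fli1 arrays at 18 and 28 hpf also had the lowest 99th percentiles of intensity, 3059 and 3281 against 10108 at 24 hpf. Cardiac muscle genes had a median of -0.51 from 18 to 24 hpf (percentile 1.05, and 2.67 under 75th percentile scaling).

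Counts within Fli1 cells moved with the scaling. From 18 to 24 hpf 296 were higher and 226 lower, from 24 to 28 hpf 487 and 593, and from 18 to 28 hpf 460 and 431. Higher ones made up 56.7%, 45.1% and 51.6%, against 81.5%, 21.1% and 46.0% under 75th percentile scaling and 84.5%, 23.9% and 61.9% with the authors' scaled values.

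Skeletal muscle and erythroid genes were higher as lists in whole embryos at 24 than at 18 hpf, while the cardiac muscle and myeloid lists did not stand apart. The calcium pump atp2a1 was at least 40.5-fold higher, hbbe1 at least 27-fold, hbae1.1 17.8-fold, the cardiac myosin light chain gene cmlc1 at least 10.2-fold, the crystallin cryba1b at least 9.09-fold, lyz at least 10.7-fold, the retinol carrier rbp4 at least 12.8-fold, the slow muscle troponin tnnc1b at least 8.97-fold and the collagen chaperone serpinh1b at least 4.82-fold. Lower were the transcription factor gene gabpa (at least 9.82-fold), the urate oxidase uox (at least 13.2-fold), hspb1 (9.39-fold), krt18a.1 (7.45-fold) and the RNA-binding gene lin28ab (4.33-fold). The signals of gabpa, uox and hspb1 stood out on the 18 hpf whole-embryo array alone, where the other uox probe did not follow, and those of rbp4 and cryba1b on the 24 hpf one alone. Skeletal muscle genes had a median of 0.99 (percentile 100), with 11 of 23 members 2-fold higher and none lower, and erythroid genes a median of 0.49 (percentile 100), with 7 higher and none lower. Cardiac muscle genes had a median of 0.04 (percentile 66.0, and -0.02 with the authors' scaled values) and myeloid and haematopoietic progenitor genes one of -0.08 (percentile 48.3). Matrix genes (0.44, percentile 99.7), neural genes (0.22, percentile 99.4), yolk, liver and gut genes (0.20, percentile 99.0) and cell cycle genes (0.14, percentile 99.2) stood apart upward, and ribosomal protein genes (-0.38, percentile 0.12) downward. With only genes above background on all 6 arrays the neural percentile was 23.6, with the direction reversed, that of yolk, liver and gut 69.9 and that of cell cycle 94.6. With the mean over the probes of a gene the ribosomal percentile was 71.8. Under 75th percentile scaling it was 5.4, and with the empty spots as background the neural one was 95.07, both inside the random lists. In all, 334 genes and unnamed probes were 2-fold higher and 238 lower, against 438 and 371 under 75th percentile scaling and 463 and 462 with the authors' scaled values. Higher ones made up 58.4%, 54.1% and 50.1% in that order. The endothelial median was -0.01 (0.01 under 75th percentile scaling).

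**Figure D3:**
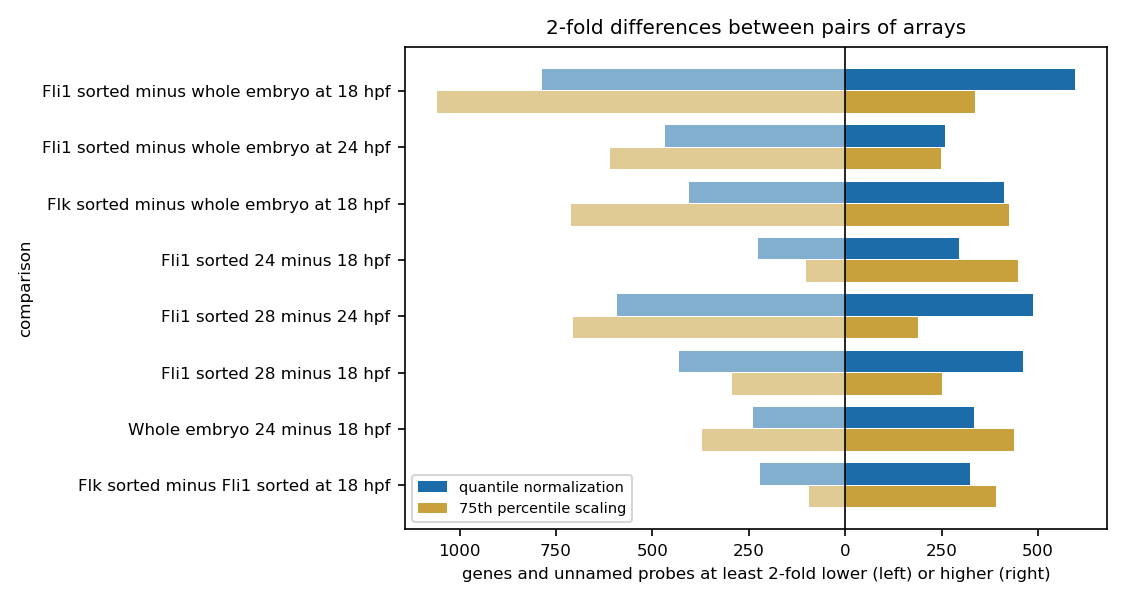
Number of genes and unnamed probes at least 2-fold higher (right) or lower (left) in each comparison of 2 arrays, after quantile normalization (blue) and after 75th percentile scaling (yellow). For Fli1 cells against whole embryos at 18 hpf the bars are 596 higher and 785 lower after quantile normalization and 337 and 1059 after 75th percentile scaling.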

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

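The opposite directions at 18 and 24 hpf below were not tested, since each rests on single arrays. Of the tests, that of a weaker Flk signal and the direction of erythroid genes with stage were chosen only after the result was seen.

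Some results for Fli1 cells against whole embryos had opposite signs at 18 and 24 hpf. Medians were 0.15 (percentile 63.5) and -1.01 (0) for skeletal muscle genes, 0.14 (64.1) and -0.16 (0.79) for cell cycle genes, and -0.53 (0.01) and 0.11 (9.57) for ribosomal protein genes. The muscle and cell cycle values at 18 hpf thus lay inside the random lists. The ribosomal 0.11 lay below its random median of 0.23, so against genes of like signal the ribosomal list was not opposite at the 2 stages. Under 75th percentile scaling the 18 hpf values for muscle (-0.13, random median -0.14) and cell cycle (-0.29, random median -0.16) changed sign. So did the 24 hpf value for ribosomal proteins (-0.02, random median 0.01). Among named genes, the muscle calcium pump atp2a1 gave 1.95 and -2.63, the collagen chaperone serpinh1b 2.72 and -2.18, and the heart and artery factor tbx20 0.78 and -1.62. The chromatin gene cxxc1a gave 5.03 and -0.58. Going the opposite way were klf17 with -0.58 and 0.88, the antiproliferative gene btg1 with -2.38 and 1.2, and the RNA-binding gene lin28ab with -0.92 and 1.85. These gene values are differences of normalized signal, and the dimmer side was not required to be above background, so their sizes are not bounded as the folds above are.

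Erythroid genes were higher in Fli1 sorted cells than in whole embryos. Of 16 members 12 were higher at 18 hpf and 14 at 24 hpf. The globin probes alone were argued against, since the 13 other members had a median of 0.47 over both stages, at percentile 98.76 of random lists. Of these 13, 9 were higher at 18 hpf and 11 at 24 hpf. The random lists take genes as independent, while the estimated correlation among the 16 erythroid genes was 0.393. The percentile can therefore be too extreme. Red cells or their precursors with reporter signal in the sorted gate, or red cells passing the gate without it, may both raise these genes, and no measurement here separates them. With no filter on dim probes the percentile at 18 hpf was 97.04, inside the random lists.

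Erythroid genes were lower in the Flk array than in the Fli1 arrays. A Flk array taken at 24 hpf was argued against as the reason, since erythroid genes were higher at 24 than at 18 hpf in Fli1 cells (0.94) and in whole embryos (0.49), and Flk cells lay below Fli1 cells of both stages (-0.41 and -1.44). Of 42 other genes that differed 2-fold with stage in both, 12 lay nearer the 24 hpf Fli1 level in Flk cells, 28.6%, fewer than the 2 in 3 set in advance for that stage. The exact 95% interval, 15.7 to 44.6, takes genes on single arrays as independent, which they are not. Of 572 genes that differed 2-fold with stage in whole embryos, whatever their change in Fli1 cells, 281 lay nearer the 24 hpf Fli1 level. The Spearman correlation of Flk cells was 0.79 with Fli1 cells at 24 hpf and 0.761 at 18 hpf. Which of the 2 stages given is right was not settled. A weaker Flk signal was argued against by 42.6% of probes above background, the highest share of the 6 arrays, against 24.7% on the Fli1 array at 18 hpf. That share describes dim probes, and the globins are bright. The 99th percentile of intensity was 9241 on the Flk array, 3059 on the Fli1 array at 18 hpf and 10108 at 24 hpf. A weaker bright signal is thus not excluded for the comparison with 24 hpf. A difference between the cells that the 2 reporters mark stays open, as untested.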

How the results depend on the processing

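The empty spots as background, the joined scan settings, the fit of 2 whole-embryo arrays against Fli1 cells at 24 hpf and Flk cells, and the counts over both stages are tests chosen only after the data were seen. Each condition had 1 array, so arrays could be paired by stage alone, as in the fit with stage as a block. Where only 1 whole-embryo array was left, limma takes it to vary like the sorted arrays. Of 1995 log2 differences of named genes recomputed under the alternatives, 5 that were at least 2-fold changed sign. Of the others, 353 moved by at least the SD of the control spots and 1637 by less. Sign changes of differences below 2-fold are among these others and were not counted. Genes near background are limited by signal, since 17.8% of probes were above background on all 6 arrays. Unless stated, the cause of a change was not tested.

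With 75th percentile scaling, Fli1 cells against whole embryos at 18 hpf had 337 genes and unnamed probes 2-fold higher, and both stages had 50 higher and 283 lower. Flk cells against whole embryos had 710 lower, Fli1 cells from 18 to 24 hpf 448 higher and 102 lower, from 24 to 28 hpf 189 higher, from 18 to 28 hpf 250 higher, whole embryos 371 lower, and Flk against Fli1 cells 95 lower. By limma 6 rose and 89 fell, 45 of them among the 47 found by quantile normalization. The endothelial percentile at 24 hpf was 96.8, the cardiac one from 18 to 24 hpf in Fli1 cells 2.67 and the ribosomal one in whole embryos 5.4, all inside the random lists, and lamb1a at 18 hpf turned to -1.36.

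With the authors' scaled values, the counts were 228 higher and 1428 lower at 18 hpf, 791 lower at 24 hpf, 46 higher and 393 lower at both stages, and 863 lower in Flk cells against whole embryos. Fli1 cells from 18 to 24 hpf had 574 higher and 105 lower, from 24 to 28 hpf 230 higher, from 18 to 28 hpf 248 lower, whole embryos 462 lower, and Flk against Fli1 cells 592 higher and 81 lower. By limma 6 rose and 106 fell, the endothelial fry adjusted p was 0.0602, the endothelial percentile at 24 hpf 97.49 and the yolk, liver and gut one in Flk cells 3.12, and lamb1a turned to -1.65.

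With only genes above background on all 6 arrays, fewer genes entered. Fli1 cells against whole embryos had 371 higher and 178 lower at 18 hpf, 122 and 85 at 24 hpf, and 32 lower at both. Flk cells against whole embryos had 173 higher and 116 lower, Fli1 cells from 18 to 24 hpf 67 and 98, from 24 to 28 hpf 292 and 258, from 18 to 28 hpf 183 and 214, whole embryos 89 and 89, and Flk against Fli1 cells 60 and 112. By limma 13 fell, and the erythroid camera adjusted p was 0.0847. Percentiles were 9.57 for epidermis at 18 hpf, 76.24 for stress and 3.06 for yolk, liver and gut at 24 hpf, 9.33 for yolk, liver and gut in Flk cells, 97.17 for erythroid genes from 18 to 28 hpf, and in whole embryos 94.56 for cell cycle, 69.88 for yolk, liver and gut and 23.62 for neural genes, whose direction reversed.

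With no filter on dim probes, percentiles were 97.04 for erythroid genes at 18 hpf, 96.96 for erythroid genes in Flk cells and 4.47 for yolk, liver and gut at 24 hpf. Within Fli1 cells they were 5.37 for cardiac muscle from 18 to 24 hpf and 16.16 for stress from 18 to 28 hpf. With the empty spots as background these percentiles were, in the same order, 96.38, 97.27, 3.85, 4.54 and 15.8, and neural genes in whole embryos stood at 95.07. With the mean over the probes of a gene, percentiles were 79.1 for endothelial genes at 24 hpf, 4.99 for cardiac muscle from 18 to 24 hpf in Fli1 cells, 96.98 for matrix and 2.97 for ribosomal genes in Flk cells, and 71.84 for ribosomal genes in whole embryos, reversed, and tnnc1a turned to -0.07. With no background correction lamb1a turned to -1.41 and the endothelial percentile at 24 hpf was 96.99, and with the joined scan settings these were -1.36 and 94.56.

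Against whole embryos at 24 hpf, Flk cells had an erythroid percentile of 9.8 and a matrix percentile of 32.33, both reversed, and 2.7 for yolk, liver and gut. Against Fli1 cells at 24 hpf the ribosomal percentile reversed to 0.39.

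In the limma comparison, an adjusted p under 0.1 gave 15 genes and unnamed probes rising and 85 falling. A stage term gave 6 rising with the Flk array at 18 hpf and 1 with it at 24 hpf, where the fry adjusted p was 0.0775 for endothelial and 0.0775 for epidermis genes. The 4 stage-matched arrays with stage as a block gave 112 rising and 200 falling on 1 residual degree of freedom, with the variance taken mostly from all genes together. There the fry adjusted p was 0.381 for endothelial and 0.401 for epidermis genes, and the ribosomal camera adjusted p was 0.0798. The 2 whole-embryo arrays against Fli1 cells at 24 hpf and Flk cells gave 0 rising and 3 falling (833 at an unadjusted p under 0.05), with fry adjusted p of 0.0686 and 0.0686 and a ribosomal camera adjusted p of 0.189. With an estimated correlation the camera adjusted p was 0.164 for epidermis, 0.593 for erythroid and 0.593 for ribosomal genes.

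Leaving out each array in turn gave 0 to 7 genes and unnamed probes rising and 8 to 46 falling. The numbers rising and falling were 0 and 32 without whole embryos at 18 hpf (597 at an unadjusted p under 0.05), 1 and 20 without whole embryos at 24 hpf, 0 and 8 without Fli1 cells at 18 hpf (845), 2 and 29 without Fli1 cells at 24 hpf, 7 and 46 without Fli1 cells at 28 hpf, and 1 and 27 without Flk cells. Camera adjusted p ranged from 0.00208 to 0.251 for erythroid genes, from 1.88e-06 to 0.00208 for epidermis and from 0.000573 to 0.13 for ribosomal proteins. Fry adjusted p ranged from 0.0118 to 0.104 for endothelial genes and from 0.00665 to 0.0455 for epidermis. Erythroid genes lost the camera call also without Fli1 cells at 24 hpf (0.115) or 28 hpf (0.0598), ribosomal genes without Fli1 cells at 28 hpf (0.0673), and endothelial genes the fry call without whole embryos at 18 hpf (0.0686), Fli1 cells at 18 hpf (0.086) or Flk cells (0.0679). The highest values came without whole embryos at 18 hpf for erythroid and ribosomal genes, without whole embryos at 24 hpf for endothelial genes, and without Flk cells for epidermis by fry.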

Other observations

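The test below was chosen before its result was seen. Some neural genes differed with stage in Fli1 sorted cells, though the list did not stand apart. From 18 to 28 hpf 6 of 30 neural genes were at least 2-fold higher in normalized signal. They were the forebrain factor foxg1a (at least 2.76-fold), the neuronal RNA-binding gene elavl3 (2.22-fold), the proneural factor ascl1a (2.16-fold), the axon guidance mediator dpysl3 (2-fold), and otx1 and the eye field gene rx2, which were below background at 18 hpf, so that their bounds against background are below 2-fold, at least 1.66-fold and 1.01-fold. The 2 lower ones were the patterning gene zic2b (at least 3.24-fold) and tubb5 (2.55-fold). Under 75th percentile scaling 3 were higher and 1 lower, and with the authors' scaled values 4 and 1. The list median was 0.23, at percentile 89.3. These members were chosen after their values were seen.

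Proteins of the secretory pathway and the lysosome were among the genes that fell in sorted cells by limma. The prolyl isomerase of the endoplasmic reticulum fkbp11 fell by 2.54 on the log2 scale (SE 0.34, adjusted p = 0.0144), the glucosidase subunit prkcsh fell by 2.08 (SE 0.30, adjusted p = 0.0234) and the lysosomal protease ctsba fell by 2.53 (SE 0.39, adjusted p = 0.0282), each lower on all 4 sorted arrays. The chaperone hspa5 of the same compartment did not pass (1.58, adjusted p = 0.126) and was higher at both 18 and 24 hpf. These genes were also picked after their values were seen and belong to no list fixed beforehand, so no theme was tested.

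High signal on 1 array alone was seen for 25 genes and unnamed probes that exceeded every other array by at least 3 on the log2 scale, of which 14 were named. In normalized signal, the homeobox gene hoxc4a exceeded the next array by 8.70 on the Fli1 array at 18 hpf, where it was saturated. On the Flk array zgc:63470 did so by 6.85 and rdh8b by 5.75. The organizer gene gsc exceeded the next array by 6.79 and the glycine decarboxylase gldc by 5.81 on the Fli1 array at 28 hpf. The next array was not required to be above background, so these gaps are not exact sizes. A signal of the spot and not of the transcript could give this, and then another probe of the same gene would stay level. Of the 4 genes with another probe, 0 had one at least 2-fold above every other array on that array. This met the share of at most 1 in 4 set in advance for a spot signal. Yet 4 genes were held too few to decide, a limit that was not part of that prediction.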
